A study of Mus musculus with 12 samples.

How the data were processed

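Liver RNA of 12 mice was analysed from 2 tables, HFD against chow and PCN against vehicle, with 3 mice per group. Groups were taken from the labels. Per the submitters' processing notes the tools were HISAT2, HTSeq and DESeq2 and the genome GRCm38 (mm10); their versions, roles and settings, and whether counting used strand, are not given in the sources used here. The deposited columns are raw read counts per gene for each mouse, beside the authors' mean, log2 fold change, its standard error, p-value and adjusted p-value, per the file headers.

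The tables hold selected genes only. All 336 diet rows have an absolute deposited log2 fold change of at least 0.6 and an adjusted p of at most 0.0474; the 33 PCN rows have the same fold limit and an adjusted p of at most 0.09547. From the Benjamini-Hochberg relation between p and adjusted p, the authors tested about 24980 and 25270 genes, and the last listed gene ranked 404 and 40, so 68 and 7 genes ranked above it are not among the rows. The adjusted p of 1 gene, Chd4, was out of rank. Size factors were recovered by solving the authors' mean column for each mouse, with a largest gap of 0.0051 counts, the size of its rounding. They ran from 0.8286 to 1.1372 in the diet table and from 0.7373 to 1.2576 in the PCN table. Total library sizes are unknown, so no share of a library was computed. All IDs were found in GENCODE M21 (336 and 33), with identical coordinates for 322 and 32; positions are 1-based on GRCm38.

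The plan made before the data were examined was edgeR's quasi-likelihood test with TMM scaling, a filter on low counts and a Benjamini-Hochberg adjusted p under 0.05. It presumed a table of all genes. On rows selected for having changed, TMM centres the folds on changed genes (it moved the median log2 fold change by -0.64 in the diet table and by -0.49 in the PCN table), the dispersion trend comes from selected genes, and adjustment over the listed genes repeats the authors' selection. edgeR was therefore run with the recovered size factors and adjusted over all genes the authors tested. Only after its counts had been seen (8 higher and 1 lower on HFD, 2 and 0 with PCN) was it decided to lead with the authors' adjusted p, the one test that saw all genes. That decision departs from the plan and was informed by the results. The counts of the planned test and of the edgeR fit are given with the numbers of genes called, with the shared genes and, for the main diet lists, after the list counts. edgeR borrows spread across the selected genes only, and with the recovered size factors it is the stricter reading.

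Versions were edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and R 4.3.3, with Python 3.11.15 and scipy 1.17.1. filterByExpr kept 331 of 336 and 33 of 33 genes. The edgeR fit was tested on simulated data in which all genes shared 1 dispersion, estimated from the listed genes (0.0621 for diet, 0.0663 for PCN). With 336 genes, adjusted over all tested genes, it called 25.3% of genes with a true log2 fold change of 1 and 97.8% at 2. With 33 genes and the PCN dispersion it called 6.7% and 79.5%. The simulated genes had no dispersion of their own, so these shares are not the power of the fit on the real data. Standard errors of edgeR folds were taken as the absolute log2 fold change over the square root of F. Folds in the text are ratios of group means of normalized counts. With 3 mice against 3, a permutation of 1 gene cannot give p below 0.1, and no such test was run.

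The genes named were set before the data were examined: the 8 largest rises and falls with an adjusted p under 0.05, a mean count of at least 10 and a name that is not predicted, the 4 smallest adjusted p in each direction, the 2 called members of each list with the smallest adjusted p, and all shared genes. Other list members, Anxa2, Gm43305, Ciart, Tnxb and Cdh1 were named after their values were seen. Some genes that the rule names are not reported here. The 26 gene lists were also fixed beforehand. A table of selected genes gives no background for enrichment, so only the direction of members among called genes was tested. Alternatives were stricter thresholds, minimum counts, names that are not predicted, Bonferroni adjustment, TMM, DESeq2, no filter and leaving out each mouse. The vehicle injection comparison and the adjusted p under 0.1 on HFD were left out because the tables do not allow them. No pseudocount was varied as an alternative. A pseudocount of 0.5 on the group means served only to compare their ratios with the deposited folds. Genes that overlap on the genome (such as Txnip and Gm15441, or Snora23 and Ipo7) and the Mup, Cyp2a and Gstp families have uncertain counts. Intervals cover counting error or gene counts as stated. The p-values of the authors' test and of the edgeR and DESeq2 fits cover the spread between these mice. Those of Fisher's exact test and the hypergeometric test rest on counts of genes, taken as independent, and hold no spread between mice.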

Results

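RNA from the livers of 12 PXR-deficient C57BL/6N mice was sequenced, 1 library per mouse and 3 mice in each of 4 groups. PXR (the pregnane X receptor, encoded by Nr1i2) is a nuclear receptor that turns on drug-metabolizing enzymes when bound by foreign compounds, and pregnenolone-16alpha-carbonitrile (PCN) is its standard rodent ligand. From 6 weeks of age the mice ate regular chow or a high-fat diet (HFD) for 18 weeks. Of the HFD-fed mice, 3 have no treatment in the labels, 3 received vehicle containing 30% DMSO and 3 received PCN at 50 mg/kg, injected once a day for 4 days. The labels give no sex, and mice are named here by group and mouse number. The authors' deposited tables hold raw counts per mouse for genes that their own test had selected, 336 genes for HFD against chow and 33 for PCN against vehicle, so the total depth of each library is unknown. Counts summed over the listed genes ranged from 547431 to 920106 per mouse in the diet table and from 34989 to 103036 in the PCN table. The stearoyl-CoA desaturase gene Scd1 alone took 44.6% to 69.7% of the former sums, and the tyrosine aminotransferase gene Tat took 24.2% to 36.8% of the latter. Values below are normalized counts, that is counts divided by the authors' size factors as recovered from their mean column, given as mean ± SD over 3 mice. Nr1i2, the deficient gene, was not analysed here because it is not among the rows held, so the genotype could not be checked.

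The first comparison asked which liver genes differed between obese and chow-fed mice lacking PXR. Among the authors' calls, 6 of 23 stellate cell and fibrosis markers, 6 of 25 fatty acid and triglyceride synthesis genes and 8 of 19 interferon response genes were higher on HFD. Lower were 4 of 30 genes on a list of fatty acid oxidation genes and PPARalpha targets. As sets, 0 of 10 lists passed the test of direction (Fisher's exact test, smallest adjusted p = 0.152). At these list sizes that test could not pass a list whose called members all rose, so the result does not speak against such lists. Cyp2a22, a cytochrome P450 gene, rose from 44.4 ± 19.1 in chow-fed mice to 615 ± 76.6 in HFD-fed mice (SD, n = 3 each), 13.9-fold. Col3a1, which encodes a fibrillar collagen, rose 4.91-fold, from 270.1 ± 10.9 to 1326 ± 412 (SD, n = 3 each). Avpr1a, which encodes a vasopressin receptor, fell from 420.3 ± 192 to 53.2 ± 15.0 (SD, n = 3 each), 7.91-fold lower. In the authors' deposited table, at an adjusted p under 0.05, 215 genes were higher and 121 lower, every one of them with an absolute log2 fold change of at least 0.6. The median ratio of group means was 2.30-fold among the higher genes and 1.99-fold lower among the lower genes.

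These calls rest on the authors' test, which covered about 24980 genes, and "rose" and "fell" below mean that a gene passed it. The planned test, edgeR's quasi-likelihood test with TMM scaling over the listed genes, called 66 higher and 119 lower after Benjamini-Hochberg adjustment over those genes, and edgeR with the authors' size factors, adjusted over all genes tested, called 8 higher and 1 lower (212 and 119 at an unadjusted p under 0.05). The 8 became 1 without chow mouse 707, 2 without chow mouse 670 or HFD mouse 659, 3 without chow mouse 695 or HFD mouse 696 and 7 without HFD mouse 669; the 1 became 2 without chow mouse 670 and 0 without each of the other 5 mice.

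The genes called higher by that last fit were Cyp2a22, Cyp2a4, Themis, Gstm3, Col3a1, Fbf1, Lgals1 and Anxa2, and the gene called lower was Avpr1a; Anxa2 was named after its values were seen. For Cyp2a22 the edgeR log2 fold change was 3.81 (SE 0.30, adjusted p = 0.0045), on chromosome 7 from 26931631 to 26939384 of GRCm38. Cyp2a4, a steroid hydroxylase gene on chromosome 7 from 26307169 to 26315088, rose 10.98-fold, from 24.6 ± 1.85 to 269.8 ± 102 (SD, n = 3 each). Both belong to the Cyp2a family. No reads were held, so whether reads of similar family members were counted for either gene could not be checked. Themis, a gene of T cell development on chromosome 10, rose from 32.3 ± 23.5 to 331 ± 36.1 (SD, n = 3 each). Lgals1, which encodes galectin-1, rose 4.67-fold and Fbf1 rose 5.36-fold. In the authors' deposited table the log2 fold changes were 3.13 for Cyp2a22, 2.59 for Cyp2a4, 2.33 for Themis and -2.22 for Avpr1a. In absolute size, the deposited values are smaller than the log2 ratios of group means, with 0.5 added to each mean, in all 336 rows, as in a table of shrunken estimates.

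**Figure D1:**
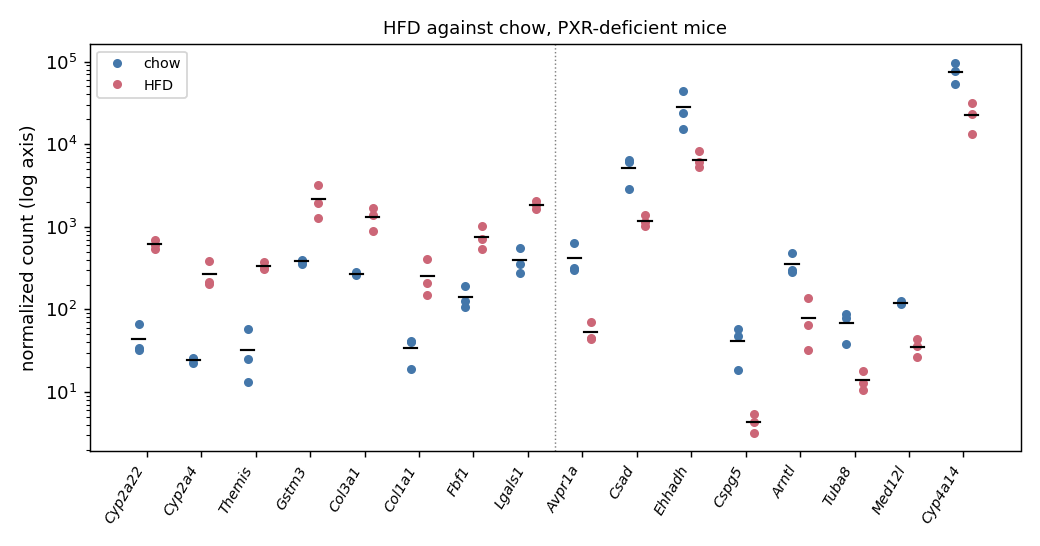
Normalized counts (log axis) of the 8 genes with the largest deposited rise on HFD and the 8 with the largest fall. These were ranked among called genes with a mean count of at least 10 and a name that is not predicted. Rises stand left of the dotted line. Each point is 1 mouse, blue for chow and red for HFD, with a black bar at each group mean. For all 16 genes the 3 HFD mice lie on one side of the 3 chow mice.

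Of 23 stellate cell and fibrosis markers, 6 rose and none of those listed fell. Besides Col3a1 these were Col1a1, which encodes the main chain of type I collagen and went from 33.7 ± 12.6 to 256 ± 135 (SD, n = 3 each), Col1a2 (3.41-fold), Col6a3 (2.36-fold), Col5a1 (1.80-fold) and the intermediate filament gene Vim (1.63-fold). Mouse 659 had the highest Col1a2 value of the HFD group, 747 against 451 and 334. Of 25 genes of fatty acid and triglyceride synthesis, 6 rose. Srebf1, which encodes the lipogenic transcription factor SREBP-1, rose 2.90-fold, from 615 ± 184 to 1781 ± 277 (SD, n = 3 each). Scd1 rose 1.64-fold, from 300480 ± 19479 to 492906 ± 72892 (SD, n = 3 each), and Thrsp, Pklr, Fasn and Elovl6 rose as well. Of 22 lipid droplet and fatty acid uptake genes, 6 rose and 1 fell. The fatty acid transporter gene Cd36 went from 1438 ± 522 to 4171 ± 1018 and the acyltransferase gene Mogat1 from 20.3 ± 7.59 to 105.3 ± 41.4 (SD, n = 3 each), while Plin5, which encodes a lipid droplet coat protein, fell 1.85-fold.

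Of 30 genes of fatty acid oxidation and PPARalpha targets, 4 fell and none of those listed rose. Ehhadh, the peroxisomal bifunctional enzyme gene, fell 4.30-fold, from 27900 ± 14720 to 6490 ± 1517 (SD, n = 3 each). Cyp4a14, a fatty acid omega-hydroxylase gene, fell 3.34-fold, from 75713 ± 21425 to 22656 ± 8949 (SD, n = 3 each), and Cyp4a31 and Acot1 fell 3.22-fold and 2.04-fold. Both cholesterol synthesis genes listed fell, Cyp51 by 1.70-fold and Sqle by 2.38-fold. Among 19 interferon response genes, 8 rose, between 1.73-fold for Gbp7 and 2.26-fold for Ifit3, which went from 102.4 ± 19.9 to 232 ± 47.5 (SD, n = 3 each). The macrophage list gave 2 rises, Itgax and Mmp12, at low counts (7.33 ± 5.17 to 37.9 ± 8.27 for Itgax, SD, n = 3 each).

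**Figure D2:**
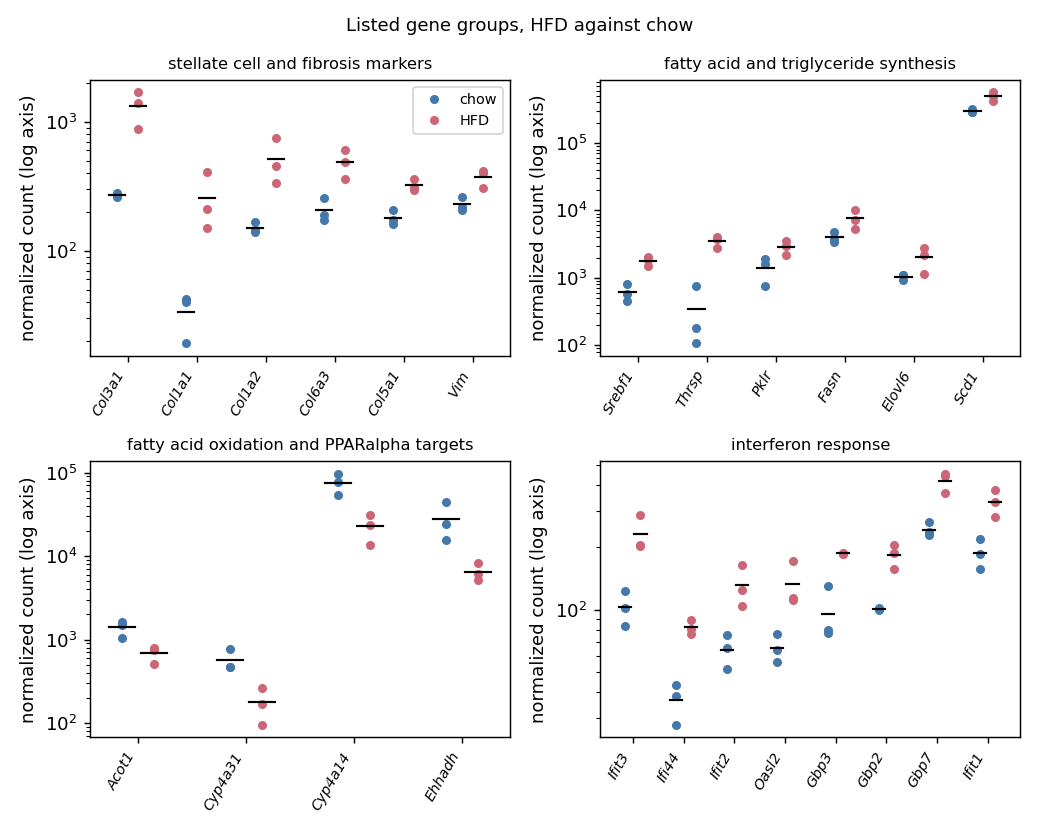
Normalized counts (log axis) of the called members of 4 gene lists in chow (blue) and HFD (red) mice, 1 point per mouse, with a black bar at each group mean. The 4 called genes of the list of fatty acid oxidation and PPARalpha targets are lower on HFD and the members of the other 3 lists are higher.

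Of 38 PXR and CAR target genes of drug metabolism, 6 rose in these mice lacking PXR. Gstm3, a glutathione transferase gene, went from 381 ± 23.0 to 2142 ± 963 and Gstm2 from 928 ± 218 to 2471 ± 256 (SD, n = 3 each), and Slco1a4 and Gstt1 rose 4.48-fold and 1.66-fold. Cyp2b13 had no counts in the 3 chow mice and 24.4 ± 19.4 in HFD mice (SD, n = 3), at least 23.5-fold higher against a floor of 3 counts over the chow group; without HFD mouse 659, at 46.1, the bound was 13.1-fold. Among 20 female-biased liver genes 4 rose (Cyp2a4, Cyp2b13, Hao2 and Fmo2), and among 22 male-biased genes 3 fell (Mup20, Cyp4a12a and Gstp1). Gstp1 went from 4679 ± 718 to 1896 ± 288 and Mup20 from 11891 ± 2081 to 6197 ± 495 (SD, n = 3 each). Both belong to families whose members may share reads, which could not be checked. Among 20 circadian clock genes, Per2 rose 2.94-fold, while Arntl fell 4.52-fold and Nfil3 2.40-fold. Among NRF2 targets Gstm2 and Gstm3 rose and Gstp1 fell. Single called members were Slc2a2 (glucose metabolism, 1.86-fold higher), Btg2 (immediate early genes, 2.25-fold higher) and Atf5 (ER stress, 2.22-fold lower). The lists of bile acid, lymphocyte, endothelial, cholangiocyte, adipocyte, pancreatic acinar, erythroid, acute phase, cell cycle, glucocorticoid receptor and mitochondrially encoded genes had 0 members among the rows.

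These list counts are of the authors' calls. With edgeR over all genes tested, Col3a1 of the stellate list passed, as did Cyp2a4 and Gstm3 of the PXR and CAR list, and 0 members of the synthesis, lipid droplet, oxidation, interferon, male-biased and clock lists did (all 331 genes fitted were under 0.05 unadjusted). The adjusted p of edgeR was 0.118 for Srebf1, 0.156 for Ehhadh and 0.239 for Ifit3. With TMM over the listed genes, 3 stellate, 2 synthesis and 0 interferon genes were called higher. All 4 genes of the oxidation and PPARalpha list were called lower. A list's direction was tested against that of the other called genes with Fisher's exact test, two-sided. Of 10 lists with at least 3 called members, 0 passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.152). Under 0.05 unadjusted were 2, fatty acid oxidation and PPARalpha targets (exact p = 0.0163) and male-biased genes (exact p = 0.046). Most called genes rose, so a list of these sizes could not pass by rising. Even 6 of 6 members higher gave exact p = 0.0913 and 8 of 8 gave 0.0546, before adjustment. The 0 thus does not speak against the lists that rose. The test takes genes as independent.

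The largest falls also included Csad, a taurine synthesis gene (4.30-fold, from 5109 ± 1949 to 1189 ± 183, SD, n = 3 each), Cspg5 (9.52-fold), Tuba8 (4.93-fold) and Med12l (3.39-fold). Tuba4a, which encodes an alpha-tubulin, had the smallest deposited adjusted p among the lower genes and went from 1961 ± 51.4 to 883 ± 18.3 (SD, n = 3 each). Gstp-ps, a glutathione transferase pseudogene, fell 2.49-fold, and its counts cannot be separated from those of Gstp1. In 334 of the 336 genes the 3 HFD mice lay wholly above or below the 3 chow mice, and the exceptions were Tnxb and Cdh1. Chance gives this for 10% of unselected genes, but these genes had been selected on the same grouping, so the count is no separate evidence.

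The second comparison asked whether PCN still altered gene expression in obese mice that lack its receptor. Among the rows held, the largest rise was in Ppp1r3c, which encodes a glycogen-targeting subunit of protein phosphatase 1. It rose 4.06-fold, from 546 ± 109 with vehicle to 2217 ± 1096 with PCN (SD, n = 3 each). In the authors' test its p was 1.3e-12 and its adjusted p 1.65e-08. With about 25270 genes tested, these values place a gene that is not among the rows above Ppp1r3c by p. Tat, a gluconeogenic amino acid catabolism gene, rose 1.85-fold, from 12804 ± 2395 to 23693 ± 7441 (SD, n = 3 each). Cd163, a macrophage scavenger receptor gene, rose 1.99-fold, from 570.4 ± 103.6 to 1135 ± 178 (SD, n = 3 each). Smad9, which encodes a BMP signal transducer, fell 2.71-fold, from 332 ± 136 to 122.6 ± 17.0 (SD, n = 3 each). In the authors' deposited table, at an adjusted p under 0.05, 17 genes were higher and 10 lower, out of about 25270 tested.

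The planned edgeR test with TMM scaling over the 33 listed genes called 7 higher and 12 lower, and edgeR with the authors' size factors over all genes tested called 2 higher, Ppp1r3c (log2 fold change 2.02, SE 0.32, adjusted p = 0.000137) and the predicted gene Gm43305, and 0 lower (12 at an unadjusted p under 0.05; DESeq2 refitted to the listed genes also gave 0). Without PCN mouse 688, and likewise without PCN mouse 706, that count was 0 in both directions. It was 4 higher and 4 lower without vehicle mouse 705, and 3 higher and 1 lower without vehicle mouse 682. The Ppp1r3c values of the PCN mice were 3481 in mouse 688, 1543 in mouse 698 and 1626 in mouse 706.

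Other rises were in the sodium-calcium exchanger gene Slc8a1 (2.04-fold), Shld2 (2.07-fold), Kcnk5 (1.93-fold), Ccdc151 (2.78-fold) and the small nucleolar RNA gene Snora23 (2.50-fold, from 259 ± 93.6 to 649 ± 65.8, SD, n = 3 each). Snora23 lies within Ipo7 on chromosome 7 from 110046364 to 110046547, so its counts cannot be separated from reads of that host gene. The falls included the cytokine signalling inhibitor gene Socs2 (2.21-fold, from 220.9 ± 7.91 to 100.1 ± 37.5, SD, n = 3 each), Mthfd1l (1.99-fold), the methyltransferase gene Inmt (1.76-fold) and the galactosyltransferase gene B4galt5 (1.70-fold). Of the 24 glucose metabolism genes 2 rose (Ppp1r3c and Tat), and of the 16 glucocorticoid receptor targets 1 rose (Tat). Of the 38 PXR and CAR targets 1 fell, Cyp2a4, which is also on the female-biased list. The clock gene Ciart was listed but did not pass the threshold, at 264 ± 40.4 with vehicle and 468 ± 110 with PCN (SD, n = 3 each). The remaining lists had 0 members among the rows, and no list had the 3 called members that the direction test needs.

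**Figure D3:**
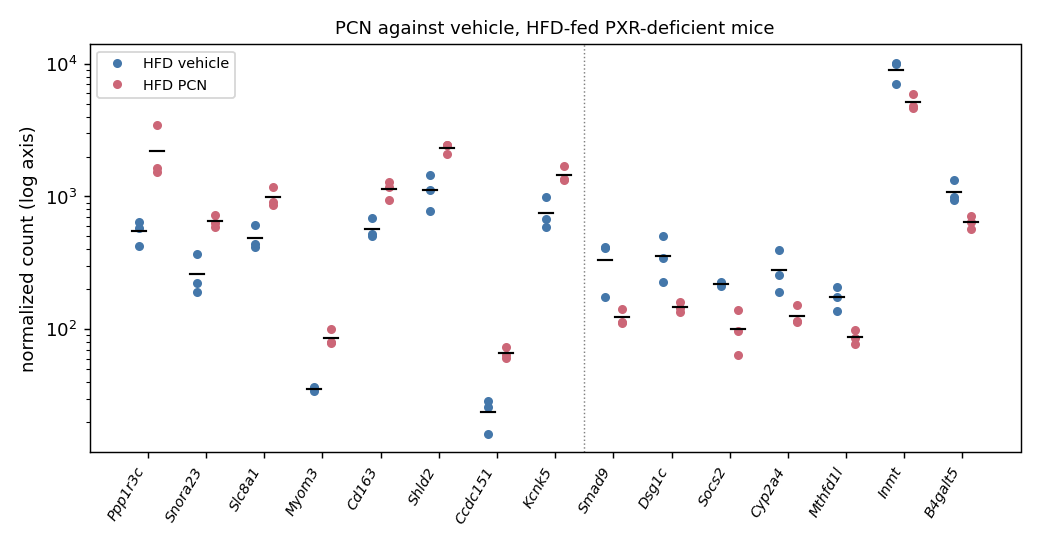
Normalized counts (log axis) of the 8 genes with the largest deposited rise on PCN and 7 of those with the largest fall. These were ranked among called genes with a mean count of at least 10 and a name that is not predicted. Rises stand left of the dotted line. Each point is 1 mouse, blue for vehicle and red for PCN, with a black bar at each group mean. For Ppp1r3c the PCN mice lie at 3481, 1543 and 1626, above all 3 vehicle mice.

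The last comparison asked whether diet and PCN moved the same genes. Of the genes called in each comparison 3 were shared: Cyp2a4 and Dsg1c were higher on HFD and lower with PCN, and Myom3 was higher in both. With edgeR over all genes tested 0 genes were shared, since of these 3 genes 0 passed with PCN (unadjusted p = 0.00135, 0.000256 and 0.000706), and with TMM over the listed genes 2 were, Cyp2a4 and Dsg1c. With PCN, Cyp2a4 went from 279 ± 104 to 126.7 ± 21.5, Dsg1c from 359 ± 139 to 146 ± 13.4 and Myom3 from 35.5 ± 1.27 to 86.5 ± 12.4 (SD, n = 3 each). Independent lists of these sizes would share 0.363 genes (exact hypergeometric p = 0.00555, one-sided, across genes, which are not independent replicates). This takes each of about 24980 tested genes as equally likely to be called. Genes with few counts are less likely to be called in either list, so the expected number and the p may both be too small. Of the 3 shared genes 66.7% had opposite directions, where independent lists would give about 46%, a difference that 3 genes cannot resolve. The comparisons share no mice and each table was normalized separately. The effect of vehicle injection alone was not analysed here, since no single table holds both the uninjected and the vehicle-injected mice.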

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

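The choice to lead with the authors' test, the edgeR fits with recovered size factors, both edgeR settings for shared genes and list members, and the count of libraries that do not overlap were added after seeing the data. For genes higher and lower on HFD (215 and 121), the counts were 130 and 76 at an adjusted p under 0.01, 92 and 35 at a log2 fold of at least 1, 57 and 37 with Bonferroni, and 70 and 31 with the 95% interval beyond 1.5-fold; these are stricter limits on the same list. The planned edgeR test with TMM gave 66 and 119 adjusted over the listed genes, and 10 and 112 adjusted over all tested genes. DESeq2 refitted to the listed genes gave 105 and 54 adjusted over all tested genes. With recovered size factors, edgeR gave 8 and 1 over all tested genes and 212 and 119 over the listed genes alone. For PCN (17 and 10), the same stricter limits gave 7 and 4, 2 and 0, 6 and 2, and 3 and 0. TMM gave 7 and 12 over the listed genes and 1 and 8 over all tested genes. DESeq2 gave 2 and 0 over all tested genes (21 and 12 at an unadjusted p under 0.05). With recovered size factors, edgeR gave 2 and 0 over all tested genes and 21 and 12 over the listed genes alone. TMM centred the folds on changed genes, and no listed gene changed sign (0 in both tables); the cause of the other gaps between tests was not tested. Minimum counts and names that are not predicted kept all 4 counts within 1.5 times, as did an adjusted p under 0.1 for PCN (21 and 12). A fold of at least 1.5 could remove no gene, since every row already had an absolute log2 fold change of at least 0.6. Leaving out 1 mouse, edgeR called 1 to 7 genes higher and 0 to 2 lower on HFD, and 0 to 4 higher and 0 to 4 lower with PCN. The HFD count fell from 8 to 2 without chow 670, 3 without chow 695, 1 without chow 707, 2 without HFD 659 and 3 without HFD 696. The count of genes higher with PCN fell to 0 without 688 or 706 and rose to 4 without vehicle 705 and 3 without vehicle 682. The count of genes lower with PCN rose from 0 to 4 without vehicle 705 and to 1 without vehicle 682. Filtering made no difference to these counts. Shared genes went from 3 to 1 at 0.01 in both, and the share with opposite directions from 66.7% to 100% there and at a mean count of at least 50. With edgeR over all tested genes 0 genes were shared, and with TMM over the listed genes 2, with a share of 100%. No list passed under any of the 4 alternatives (0 of 6 to 10 lists, Fisher's exact test, with 1 or 2 under 0.05 unadjusted). The fold of 1.5 was among these 4 and could not change the lists. In the main setting, lists whose called members all rose could not pass at their sizes, so the 0 does not speak against them. Not run as alternatives: an adjusted p under 0.1 on HFD, a change of pseudocount and the vehicle comparison. Depth is unknown, and genes that the authors did not list cannot be read as unchanged.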

Other observations

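The gene groups in this paragraph were chosen after the tables had been seen, so their counts are descriptions and not tests. In a hand-picked and incomplete group of further matrix and matrix-associated genes, 20 rose and 4 fell on HFD. Of the 20, Thbs1 (46.9 ± 5.45 to 157 ± 53.7, SD, n = 3 each), Tnc (27.2 ± 3.20 to 81.5 ± 20.2), Col6a1 (2.67-fold) and Sparc (1.71-fold) are examples, and the 4 are Cspg5 (9.52-fold lower), Serpine2 (2.37-fold), Chsy3 (1.99-fold) and Itga5 (1.93-fold). Among glutathione transferases, 5 rose (Gstm2, Gstm3, Gstt1, Gstt3 and Gstp3) and 2 fell (Gstp1 and Gstp-ps). Of 3 inhibin and activin subunit genes, Inhbe rose 2.31-fold while Inhbc and Inhba fell 2.19-fold and 2.46-fold. The tubulin genes Tuba4a, Tuba8 and Tubb4b fell, as did the junction genes Cldn1 (2.27-fold), Ocln (1.66-fold), Marveld2 and Cdh1, the last with overlapping libraries, while Marveld1 of the same group rose. Of 11 called protein-coding cytochrome P450 genes, 4 rose (Cyp2a22, Cyp2a4, Cyp2b13 and Cyp21a1) and 7 fell, among them Cyp1a2 and Cyp39a1. Retsat and Cyp26a1, genes of retinoid metabolism, fell 1.97-fold and 2.95-fold on HFD. Txnip rose 2.0-fold and its antisense neighbour Gm15441 fell 5.0-fold; strand use in counting is not stated, so their reads cannot be separated.

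Apart from the planned direction tests of the 2 sex-biased lists, the tests in the following paragraphs were chosen after the results were seen, and all rest on genes the authors had selected. With edgeR over all tested genes, the real grouping called 9 genes on HFD and the highest of the other 9 of 10 splits called 0, so 1 split reached the real count; for PCN the real grouping called 2 and the highest other 0, again 1 of 10. With 10 splits a share under 0.05 cannot be reached, and the genes had been selected on the real grouping.

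The 6 called stellate markers rose on HFD, a pattern that a lower share of hepatocytes might give by raising all stellate cell transcripts alike. The 5 called collagens of the list did not rise alike, with edgeR log2 folds from 0.85 to 2.93. Cochran's Q was 32.9, where equal folds would give about 4, with genes taken as independent. Unequal folds would speak against that share only if these collagens came from stellate cells alone, which was not tested, so Q cannot decide. The lowest median log2 fold of the 6 stellate markers was 1.22, without HFD mouse 659, against 1.5 with all mice, so no single mouse made up that median. The markers had been called with all mice included, so the part of 1 library in their selection was not tested. A change in stellate cell activity with the diet stays open as a hypothesis and was not tested.

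The 4 called female-biased genes rose and the 3 called male-biased genes fell on HFD, but neither list passed the planned test of direction after adjustment (female-biased exact p = 0.301, adjusted 0.43; male-biased exact p = 0.046, adjusted 0.152). With all 4 called members higher, the female-biased list could not have passed, and 0.046 is the smallest p that 3 members lower can give. The test therefore does not speak against either direction. The lowest median log2 fold with male-biased genes sign-turned was 1.22, without chow mouse 695, against 1.42 with all mice. Cyp2b13 was filtered out of the fit with all mice but kept in the fit without chow mouse 695. The medians therefore cover different genes and do not show how much a single mouse contributed. These genes too had been called with all mice included, so the part of 1 library in their selection was not tested. If all mice of one group were of another sex, transcripts present in one sex only would be among the smallest p-values, yet the 44 genes with a p under 1e-08 in the authors' deposited table hold ranks 1 to 44 with 0 missing, and 0 of them lie on the X or Y chromosome. That argues against a full difference in sex, provided such transcripts were among the genes tested, as 9 listed X chromosome genes were; a mix of sexes within a group stays open. For all 7 called members, reads shared between paralogs cannot be told apart from expression, since the tables hold no reads, and a diet effect on the hormonal control of these genes may be a candidate explanation that was not tested.

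Among the 10 genes called lower with PCN, vehicle mouse 682, which has the smallest size factor (0.7373), was the highest vehicle mouse in 9. A size factor that is too small would raise every gene in 682, yet 682 was the lowest vehicle mouse in 10 of the 17 genes called higher, 58.8% (exact 95% interval 32.9% to 81.6%, across genes) against 33.3% with no preference; the interval reaches that value, so the size factor is not excluded. Without mouse 682 the median log2 fold of the genes called lower was -0.84 against -1.12, so that mouse did not make up the whole median. The genes had been called with mouse 682 included, so its part in their selection was not tested. A graded difference among vehicle mice that PCN shares, such as feeding state or time of day, may be another explanation, and no label allows a test.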
